A study of Danio rerio with 11 samples.

How the data were processed

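Stage I and stage II oocytes were compared between WT and znf706 mutant zebrafish in 8 RNA-seq libraries, 2 per genotype and stage, each made from the polyadenylated RNA of about 600 (stage I) or 150 (stage II) oocytes. The 3 CUT&Tag libraries of the series (1 IgG and 2 with an antibody against Znf706) were not analysed here. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to danRer11 with STAR 2.5.3a and quantified with Cufflinks 2.2.1. The values are FPKM, deposited as 1 merged table, and read counts were not used here. No genome was used, and gene order came from a gene table of another zebrafish assembly.

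The table holds 32197 entries for 32055 gene IDs. Exact duplicates (24) were merged, and 103 gene IDs with conflicting entries, which differ in stage I columns alone, were left out, as no entry could be preferred. This left 31952 gene IDs, 7857 of them at 0 in every library. Absolute depth is unknown, because FPKM hide it. Relative depth was read from the most common ratio of very low values between libraries, sought only near equal depth. It lay between 0.894 and 1.05 of WT stage I replicate 1, but a large difference in depth could not have been found this way. The median SD of log2 values between the 2 libraries of a group was 0.0798 to 0.111, and 169 to 266 genes differed 2-fold between them.

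Genes with at least 1 FPKM in at least 2 of the 8 libraries were tested (13862). Values were log2(FPKM + 1), with no further scaling. One limma fit with 4 group means (lmFit, contrasts.fit, eBayes with a trend in the prior; 4 residual and 3.78 prior degrees of freedom) gave 5 contrasts: mutant against WT at stage I, at stage II and averaged over the stages, stage II against stage I in WT, and the difference between the genotype effects (the interaction). Calls are Benjamini-Hochberg adjusted p under 0.05. The 25 gene lists were fixed before the data were examined, as were this design, the samples and most alternatives. Lists with at least 5 tested members (23) were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a contrast. Members were also counted with p adjusted over the list alone.

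Named genes followed a rule fixed in advance: znf706, 8 germ plasm genes (buc, ddx4, nanos3, dazl, dnd1, tdrd6, tdrd7a, piwil1), the 8 largest rises and 8 largest falls of each contrast among called genes whose libraries do not overlap between the groups, and up to 4 called members of each list. Names of uncharacterized clones were left out of the largest changes by their prefixes, which did not cover the clone-style name FQ377662.1. The text describes a selection of these genes. Genes whose call was lost on leaving out 1 library were mostly not described, and a gene that the rule named in one contrast was also followed in others. The second rrm2 copy, birc5a, rac2 and neighbours of named genes lie outside the rule and were chosen after their values were seen.

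Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, quantile normalization, median-of-ratios scaling, no trend or a robust prior, arrayWeights, the replicate number as a block (over all groups or within genotype), only the 4 libraries of a contrast, a 2-fold threshold, an estimated correlation, Spearman for Pearson correlation, and leaving out each library in turn. Entering conflicting gene IDs at the mean of their values and leaving out on and off genes were added after the data were seen.

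On and off genes were defined after the data were seen, as at least 5 FPKM in both libraries of one group and under 0.5 in both of the other. The adjacent tested gene on each side, if it did not overlap and was not itself on or off, was counted as a neighbour, and counts were set against values drawn at random from the placed genes that were not on or off, as many times as make the smallest possible p 0.0001. The test of exact 0 values was split by stage after the values were seen. Splits of the libraries within stages (18) were run through the same fit.

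On simulated data with 200 of 13862 genes changed, the fit recovered 22.4%, 70.1% and 95.5% of log2 changes of 0.5, 1 and 2 at stage I (7 false calls). It recovered 13.4%, 71.6% and 86.4% at stage II (13 false), 56.7%, 85.1% and 98.5% averaged (4 false), 23.9%, 70.1% and 95.5% for stage in WT (7 false) and 2.99%, 38.8% and 86.4% for the interaction (3 false). Of 23 lists the 1 shifted list was called and 0 others. These simulations drew the noise of each gene independently and changed far fewer genes than were called in the data. In the data the estimated correlation was 0.69 for the mitochondrially encoded and 0.64 for the ribosomal list, and -0.0076 for translation. How often correlated lists are called falsely was therefore not tested. The neighbour test on 60 simulated on and off genes found 2 neighbours moving with independent genes (mean of random draws 2.57) and 59 with genes in blocks (3.45). Work was done in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.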

Results

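Oocytes of zebrafish carrying a CRISPR/Cas9 mutation of znf706, which encodes a small zinc finger protein, were compared with wild-type (WT) oocytes at 2 early stages of oogenesis. The mutant libraries carry the genotype label MZznf706, where MZ usually stands for maternal-zygotic. Polyadenylated RNA was sequenced from about 600 stage I oocytes or about 150 stage II oocytes per library, picked by hand after enzymatic digestion of ovaries from 3-month-old females. The 8 libraries form 4 groups of 2, called biological replicates in the series text: WT and mutant at stage I, and WT and mutant at stage II. Expression was deposited as FPKM per gene without read counts, so the absolute depth is unknown. The most common ratio of very low values put the other libraries at 0.894 to 1.05 times the depth of WT stage I replicate 1. It was sought only near equal depth, so a large difference in depth could not have been found. Summed FPKM ran from 653659 to 899582, and 11992 to 12691 genes reached 1 FPKM per library. Levels are given as means ± SD over n = 2 libraries in FPKM, and log2 fold changes are on the log2(FPKM + 1) scale with their SE, which understates the change of genes with low values. The Znf706 CUT&Tag libraries of the same series were not analysed here.

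The targeted gene znf706 (ENSDARG00000056307) stood at 232 and 238 FPKM in the WT stage I libraries and at 181 and 147 FPKM in the mutant stage I libraries. Its transcript fell by 0.52 ± 0.11 on the log2 scale at stage I (adjusted p = 0.0056). At stage II it stood at 158 and 143 FPKM in WT and at 129 and 142 FPKM in mutants, a log2 fold change of -0.15 ± 0.11 that missed the threshold (adjusted p = 0.29). The difference between the stages missed it as well (interaction 0.37 ± 0.15, adjusted p = 0.091), and passed without mutant stage I replicate 1 (0.52, adjusted p = 0.024). The series text gives the allele as tsu7d but not which part of the transcript it alters, so the transcript level does not test the genotype labels.

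Libraries of one group were the most alike. Across the 13862 genes tested, the log2 values of the 2 libraries of a group correlated at r = 0.985 to 0.989. Those of the 2 genotypes at the same stage correlated at 0.923 to 0.929, and those of the 2 stages in the same genotype at 0.897 to 0.924. These are correlations across genes, which are not independent replicates. The first 3 principal components held 44.3%, 29.2% and 17.5% of the variance, and each later one 2.53% or less. Stage I libraries put 9.16% to 10.4% of their summed FPKM into their 10 highest genes, against 3.61% to 4.51% at stage II.

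The first comparison asked which transcripts differed between mutant and WT oocytes at stage I, with the genes of the germ plasm, the maternal RNA and protein aggregate that specifies primordial germ cells, as the set named in the title of the study. The largest difference in this set was in nanos3 (ENSDARG00000068255), an RNA-binding translational regulator needed by germ cells, which rose from 78.8 ± 1.39 to 344 ± 10.4 FPKM (log2 fold change 2.11 ± 0.06, adjusted p = 4.5e-07). The germ granule gene piwil1 rose from 36.4 ± 1.76 to 50.6 ± 1.27 FPKM (0.46 ± 0.07, adjusted p = 0.0015). The Tudor genes tdrd6 and tdrd7a rose by log2 0.35 ± 0.08 (adjusted p = 0.0093) and 0.53 ± 0.10 (adjusted p = 0.0048). The RNA-binding gene dazl rose by 0.47 ± 0.09 (adjusted p = 0.0045). The helicase gene ddx4 (vasa) went the other way and fell by 0.68 ± 0.13 on the log2 scale, from 80.9 ± 17.1 to 49.4 ± 1.39 FPKM (adjusted p = 0.0035). The organizer of the Balbiani body, buc, was at 1035 ± 36.8 FPKM in WT and 923 ± 66.6 FPKM in mutants, and dnd1 at 63.7 ± 4.37 and 61.3 ± 3.82 FPKM. Neither passed the threshold (adjusted p = 0.18 and adjusted p = 0.63), and the sign for dnd1 turned under both other scalings.

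In the whole germ plasm list, 10 of 26 tested members were higher and 2 lower (10 and 2 adjusted over the list alone), which camera did not call (camera adjusted p = 0.079, adjusted p = 0.56 with an estimated correlation). It did without mutant stage I replicate 1 (camera adjusted p = 0.042), with a pseudocount of 5 (0.037) and with a filter at a mean of 5 FPKM (0.029). Besides nanos3, both genes annotated hook2, a microtubule linker, rose: ENSDARG00000099235 from 24.9 ± 3.71 to 46.1 ± 1.65 FPKM (0.87 ± 0.14, adjusted p = 0.0015) and ENSDARG00000039309 from 27.7 ± 5.50 to 53.3 ± 0.962 FPKM (adjusted p = 0.028). The second call was lost without any single stage I library (adjusted p = 0.051 to 0.15). The germ plasm marker ca15b rose from 954 ± 123 to 1753 ± 8.27 FPKM (0.88 ± 0.10, adjusted p = 3.7e-04).

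**Figure D1:**
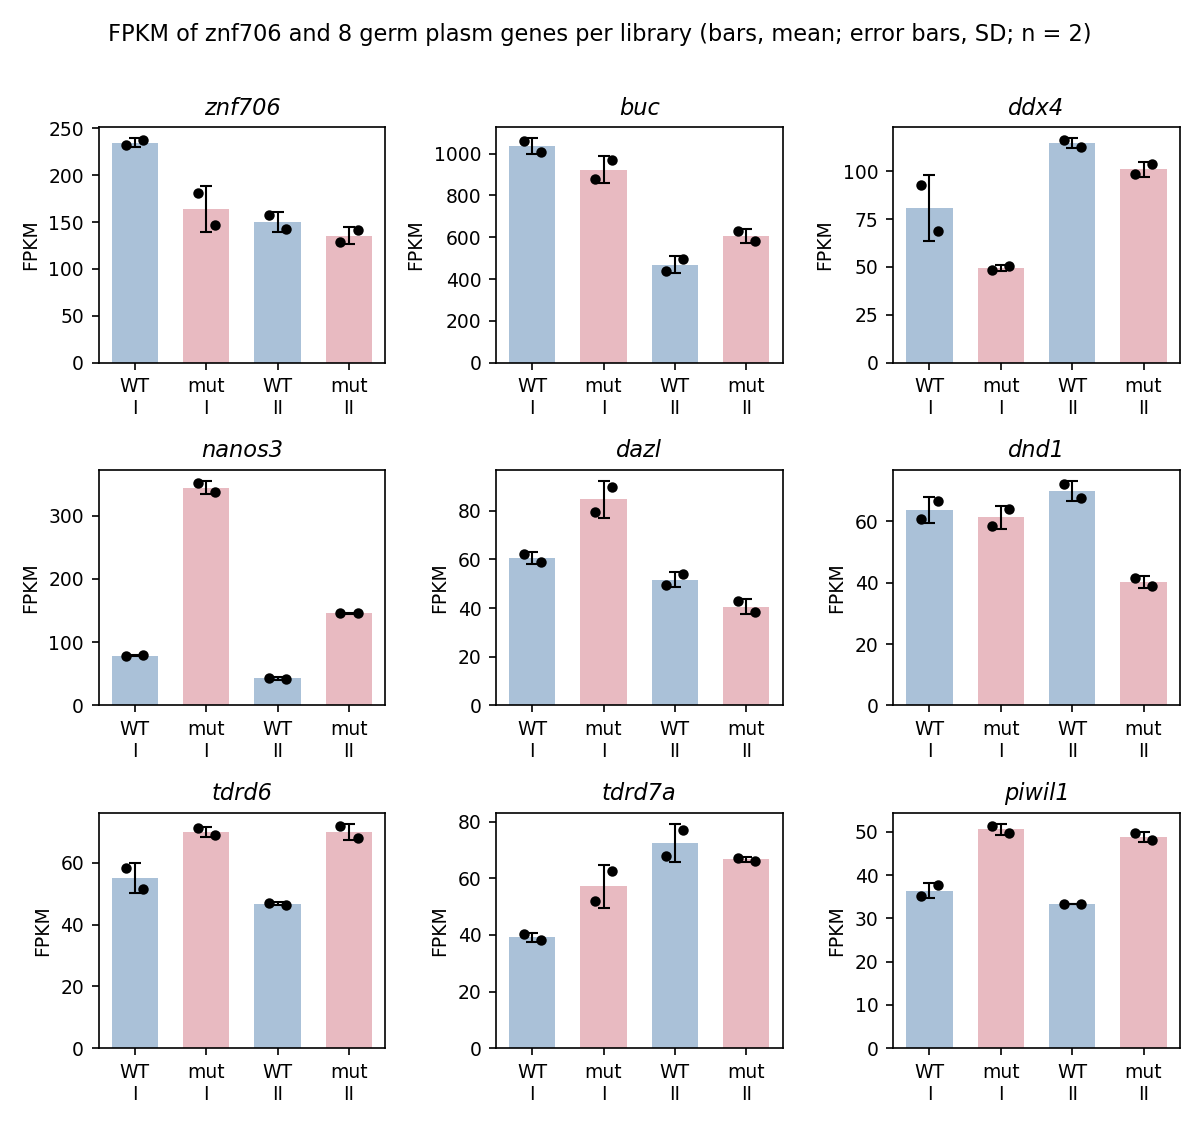
FPKM of znf706 and of the 8 germ plasm genes named in every comparison, in WT and mutant oocytes at stages I and II (y axis, FPKM, starting at 0; bars, mean; error bars, SD; points, the 2 libraries of each group). The plot shows nanos3 at 78.8 FPKM in WT and 344 FPKM in mutants at stage I, and at 42.7 and 146 FPKM at stage II.

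Across all genes at stage I, 6282 of the 13862 tested passed the threshold in limma with Benjamini-Hochberg adjustment, 2551 higher and 3731 lower in mutants, and 1835 of them changed at least 2-fold on the log2(FPKM + 1) scale. The median log2 fold change of all genes was -0.08. The share of calls that were higher was 40.6% as deposited, 51.2% after median-of-ratios scaling and 49.2% after quantile normalization. List medians below are therefore given relative to the median of all genes.

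Many of the largest changes at stage I were between a high level and almost none. Among the rises, the ribonucleotide reductase gene rrm2 (ENSDARG00000078069) went from 1.29 ± 0.317 to 729.9 ± 50.9 FPKM (log2 fold change 8.32 ± 0.14, adjusted p = 4.4e-08). A second gene annotated rrm2 (ENSDARG00000020711), which is outside the naming rule and was looked up after these values were seen, went from 1165 ± 32.3 to 694 ± 33.7 FPKM. How the deposited quantification divided reads between these copies is not given. The translation initiation gene eif1axb rose from 0.602 ± 0.0195 to 142 ± 16.6 FPKM (adjusted p = 3.7e-07). The transcription factor gene foxa rose from 0.484 ± 0.0594 to 88.2 ± 9.26 FPKM (adjusted p = 8.0e-07) and gtf3ab, for the 5S rRNA transcription factor, from 0.384 ± 0.121 to 80.5 ± 4.73 FPKM (adjusted p = 3.7e-07). The RNA-binding gene thumpd3 rose from 0.0507 ± 0.0139 to 42.6 ± 0.448 FPKM (adjusted p = 1.6e-07) and the RNA-processing gene smx5 by log2 5.42 ± 0.09 (adjusted p = 4.4e-08). The arginine methyltransferase gene prmt7 and FQ377662.1 were listed at 0 in both WT libraries and stood at 38.9 and 40.0 and at 59.2 and 44.1 FPKM in the mutant libraries (adjusted p = 3.9e-07 and adjusted p = 6.4e-07).

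Among the falls at stage I, birc5b, one of 2 survivin paralogs of the chromosomal passenger complex, dropped from 631 ± 81.9 to 0.365 ± 0.259 FPKM (log2 fold change -8.86 ± 0.18, adjusted p = 5.7e-08). The steroidogenic gene cyp11a1, which encodes the side-chain cleavage enzyme that starts steroid synthesis, fell from 212 ± 13.0 to 0.108 ± 0.0636 FPKM (-7.59 ± 0.18, adjusted p = 1.4e-07). The histone H4 lysine methyltransferase gene kmt5ab fell from 113 ± 4.22 to 0.0830 ± 0.00118 FPKM (-6.72 ± 0.12, adjusted p = 4.7e-08). The Tudor gene tdrd1 of the piRNA pathway fell from 55.7 ± 1.88 to 0.0179 ± 0.00346 FPKM (-5.80 ± 0.11, adjusted p = 4.8e-08). The condensin gene ncapg stood at 51.7 and 45.7 FPKM in WT and 0 and 0.0207 FPKM in mutants (adjusted p = 2.0e-07). The glycosylation gene alg14 stood at 134 and 136 and 0 and 0.112 FPKM (adjusted p = 4.8e-08). The exon junction gene magoh fell from 327 ± 8.07 to 6.48 ± 0.851 FPKM (adjusted p = 2.6e-07). A gene annotated qdprb2 (ENSDARG00000090118) fell from 209 ± 12.5 to 0.0730 ± 0.00147 FPKM (adjusted p = 4.7e-08). Its second copy ENSDARG00000086859 fell from 1163 ± 86.6 to 69.9 ± 3.34 FPKM (adjusted p = 2.8e-04). How reads were divided between the copies is not given. The deposited table does not say whether a level near 0 is a true absence or a failed estimate.

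Other germ cell lists at stage I moved in both directions. In the piRNA and Tudor list, 8 of 17 tested members were higher and 5 lower (9 and 5 adjusted over the list alone). The Piwi gene piwil2 rose from 24.2 ± 3.09 to 46.9 ± 10.1 FPKM (adjusted p = 0.0019), while tdrd1 fell. The list's median was 0.24 and its mean -0.14, and it did not pass as a set (camera adjusted p = 0.24, adjusted p = 0.56 with an estimated correlation). Among the meiotic prophase genes, 4 of 11 tested members were higher and 2 lower (4 and 2 adjusted over the list alone). The synaptonemal complex gene sycp3 rose from 0.249 ± 0.197 to 8.13 ± 0.158 FPKM (adjusted p = 9.9e-05). Its partner genes sycp1 and sycp2 rose from 1.42 ± 0.108 to 10.5 ± 1.03 FPKM (adjusted p = 3.0e-05) and from 0.612 ± 0.0520 to 3.64 ± 0.363 FPKM (adjusted p = 1.7e-04). The telomere-tethering gene terb1 stood at 1.56 and 1.56 FPKM in WT and at 0 and 0.0702 FPKM in mutants (adjusted p = 1.9e-04). In the oocyte and maternal-effect list, 11 of 33 tested members were higher and 5 lower (15 and 5 adjusted over the list alone). The gene figla, a transcription factor of early oocytes and their egg coat genes, rose from 15.0 ± 0.865 to 112 ± 12.6 FPKM (log2 fold change 2.82 ± 0.12, adjusted p = 2.4e-06). The gene btg4, which promotes maternal mRNA decay, rose from 673 ± 19.6 to 1375 ± 164 FPKM (adjusted p = 1.9e-04). In the cell cycle and maturation list, 14 of 34 tested members were higher and 8 lower (14 and 8 adjusted over the list alone), with a median of 0.04 and a mean of -0.13. Besides birc5b, fbxo43, an inhibitor of the anaphase-promoting complex, rose from 104 ± 4.81 to 203 ± 15.6 FPKM (adjusted p = 7.9e-05) and mki67 from 13.3 ± 0.283 to 26.0 ± 5.10 FPKM (adjusted p = 0.0010). None of these 3 lists passed as a set (camera adjusted p = 0.36, 0.082 and 0.18), and the oocyte list passed without WT stage I replicate 2 (0.016), while with a filter at a mean of 5 FPKM the oocyte and cell cycle lists did (0.044 and 0.047).

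Markers of leukocytes were higher in mutants at stage I: 8 of 12 tested members were higher and 0 lower (8 and 0 adjusted over the list alone). The median was 0.79 above that of all genes (camera adjusted p = 0.0089, adjusted p = 0.49 with an estimated correlation). The MHC class II chaperone genes cd74a and cd74b rose by log2 1.72 ± 0.30 (adjusted p = 0.0027) and 1.32 ± 0.25 (adjusted p = 0.0036). The call for cd74a was lost with a pseudocount of 0.1. Most tested markers stood at low levels. Of those at the highest levels, arhgdig rose from 29.9 ± 3.25 to 132 ± 15.4 FPKM, while rac2 stood at 26.7 ± 0.0823 and 26.2 ± 0.268 FPKM. Some markers, such as cd4-1 and coro1a, entered the test only because mutant libraries reached 1 FPKM, which favours counts of higher members. In the granulosa and theca list, 1 of 5 tested members were higher and 2 lower (1 and 2 adjusted over the list alone). While cyp11a1 was lower, the steroidogenic gene cyp17a1 rose from 47.8 ± 0.248 to 100.4 ± 5.99 FPKM (adjusted p = 2.8e-05). In the stroma, smooth muscle and endothelium list, 1 of 10 tested members were higher and 1 lower (1 and 1 adjusted over the list alone). The fibronectin gene fn1a rose from 0.360 ± 0.0155 to 4.15 ± 0.408 FPKM (adjusted p = 6.4e-05) and the keratin gene krt8 fell from 9.19 ± 1.05 to 3.96 ± 1.31 FPKM (adjusted p = 0.0048). Neither list passed (camera adjusted p = 0.81 and 0.26; relative medians -0.02 and 0.24). Of the blood and liver lists 3 genes and 1 gene were tested, too few for a set test. The blood genes slc4a1a (log2 fold change 0.68 ± 0.15, adjusted p = 0.0069) and tspo rose, and the liver gene rbp4 fell from 8.59 ± 0.272 to 3.54 ± 0.552 FPKM (adjusted p = 0.0079). The rbp4 call was lost without mutant stage I replicate 2 (-0.96, adjusted p = 0.059). The tspo call (46.4 ± 2.55 to 57.3 ± 5.08 FPKM, adjusted p = 0.027) was lost without WT replicate 1 or mutant replicate 1 (0.24, adjusted p = 0.12, and 0.21, adjusted p = 0.14). In the testis and sperm list, 4 of 9 tested members were higher and 2 lower (6 and 3 adjusted over the list alone). The list did not pass (camera adjusted p = 0.095, adjusted p = 0.56 with an estimated correlation). The gene spata18, a regulator of mitochondrial quality also known as mieap, rose from 20.5 ± 1.44 to 178 ± 7.19 FPKM (log2 fold change 3.06 ± 0.08, adjusted p = 2.6e-07).

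Genes of the unfolded protein response were lower in mutants at stage I: 3 of 28 tested members were higher and 15 lower (3 and 15 adjusted over the list alone). The median was -0.32 relative to all genes (camera adjusted p = 0.048, adjusted p = 0.56 with an estimated correlation). The endoplasmic reticulum chaperone genes dnajb9b and calr fell from 146 ± 10.1 to 6.42 ± 1.60 FPKM (log2 fold change -4.33 ± 0.14, adjusted p = 7.2e-07) and from 100.2 ± 13.7 to 44.2 ± 4.44 FPKM (adjusted p = 1.6e-04). The disulfide isomerase gene pdia6 rose by 1.84 ± 0.10 (adjusted p = 9.6e-06). The call of the unfolded protein response list was lost under 8 of the 21 other settings run with the preset correlation, among them median-of-ratios scaling (adjusted p = 0.061) and the replicate block (0.059). The 8 include leaving out any 1 of the 4 stage II libraries (0.059 to 0.065), which enter through the shared spread. Proteasome genes were also lower: 3 of 48 tested members were higher and 24 lower (4 and 27 adjusted over the list alone; relative median -0.19; camera adjusted p = 0.024, adjusted p = 0.56 with an estimated correlation). The base subunit gene psmc1a fell from 47.0 ± 4.81 to 15.5 ± 2.15 FPKM (adjusted p = 1.1e-04), while the catalytic subunit gene psmb5 rose from 40.5 ± 1.69 to 71.9 ± 0.649 FPKM (adjusted p = 5.3e-04). The list call was lost after median-of-ratios scaling (adjusted p = 0.079) and without WT stage I replicate 2 (0.083).

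The ligands and axis genes of the TGF-beta, BMP and Wnt pathways were higher in mutants at stage I, with 12 of 18 tested members higher and 1 lower (14 and 2 adjusted over the list alone). Their relative median was 0.54 (camera adjusted p = 0.0089, adjusted p = 0.52 with an estimated correlation). The ligand genes bmp7b and wnt11f2 rose at low levels, from 0.124 ± 0.0466 to 1.79 ± 0.163 FPKM (adjusted p = 0.0031) and 0.464 ± 0.0793 to 2.03 ± 0.0895 FPKM (adjusted p = 0.0032). The steroid and retinoid list had 5 of 13 tested members higher and 0 lower (5 and 0 adjusted over the list alone; relative median 0.29; camera adjusted p = 0.024, adjusted p = 0.49 with an estimated correlation). The retinoic acid hydroxylase gene cyp26a1 rose from 11.8 ± 1.79 to 36.9 ± 0.657 FPKM (adjusted p = 5.5e-05) and the steroid dehydrogenase gene hsd3b2 from 73.6 ± 4.61 to 187 ± 4.14 FPKM (adjusted p = 1.1e-05). This list call was lost without a filter on low values (adjusted p = 0.11).

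The remaining lists did not pass at stage I. The nuclear-encoded respiratory chain had 4 higher and 33 lower of 81 (4 and 33 adjusted over the list alone), camera adjusted p = 0.069. Mitochondrial dynamics and biogenesis had 6 higher and 18 lower of 47 (6 and 18 adjusted over the list alone), adjusted p = 0.24. The fission factor gene mff fell from 40.5 ± 2.38 to 17.8 ± 0.438 FPKM (adjusted p = 2.8e-05). Cytosolic ribosomal protein genes had 1 higher and 11 lower of 85 (1 and 6 adjusted over the list alone), adjusted p = 0.19. In it rpl32 stood at 992 and 338 FPKM in WT and 13.7 and 11.3 FPKM in mutants (adjusted p = 7.9e-05). Translation initiation and elongation had 14 higher and 27 lower of 72 (15 and 30 adjusted over the list alone), adjusted p = 0.49. In this list eif1b rose from 421 ± 13.3 to 1793 ± 63.4 FPKM (adjusted p = 8.1e-07) and eif4ea fell from 176 ± 1.90 to 43.8 ± 1.50 FPKM (adjusted p = 1.5e-06). Microtubule motors and tubulins had 22 higher and 9 lower of 59 (24 and 12 adjusted over the list alone), adjusted p = 0.079. Nuclear pore and transport had 14 higher and 15 lower of 57 (14 and 15 adjusted over the list alone), adjusted p = 0.65. Cholesterol synthesis had 4 higher and 8 lower of 22 (4 and 9 adjusted over the list alone), adjusted p = 0.44. The mitochondrially encoded genes had 2 higher and 0 lower of 13 (0 and 0 adjusted over the list alone), adjusted p = 0.26. The immediate-early and heat shock genes had 5 higher and 5 lower of 31 (5 and 4 adjusted over the list alone), adjusted p = 0.72. Without WT stage I replicate 1 the respiratory, ribosomal and mitochondrially encoded lists passed (adjusted p = 0.0057, 0.0045 and 0.038), and without mutant stage I replicate 1 the respiratory list did (0.042). The respiratory list also passed with a pseudocount of 5 (0.025), and both it and the ribosomal list without a filter (0.0012 and 0.029) and after quantile normalization (0.026 and 0.027). Mitochondrial dynamics passed without a filter (0.029), and microtubule motors with a filter at a mean of 5 FPKM (0.029). The immediate-early list had a median of -0.15 and a mean of -0.20 although its test pointed up, and the nuclear pore list likewise had a median of -0.05.

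At stage II the same question was asked of larger oocytes. In the germ plasm set, nanos3 again differed most, at 42.7 ± 1.83 FPKM in WT and 146 ± 0.421 FPKM in mutants (log2 fold change 1.75 ± 0.06, adjusted p = 1.4e-06). The genes tdrd6 and piwil1 rose by 0.57 ± 0.08 (adjusted p = 0.0010) and 0.54 ± 0.07 (adjusted p = 8.6e-04). The germ cell survival gene dnd1 fell by 0.78 ± 0.08 on the log2 scale, from 69.9 ± 3.19 to 40.2 ± 1.96 FPKM (adjusted p = 3.1e-04). The gene dazl fell from 51.6 ± 3.13 to 40.6 ± 3.00 FPKM (adjusted p = 0.020), a call lost without the second WT or the second mutant library (-0.28, adjusted p = 0.10, and -0.26, adjusted p = 0.12). The Balbiani body gene buc rose from 468 ± 40.8 to 605 ± 33.4 FPKM (0.37 ± 0.09, adjusted p = 0.013). This call was lost after median-of-ratios scaling (0.28, adjusted p = 0.063), without WT replicate 1 (0.28, adjusted p = 0.084) and without mutant replicate 1 (0.32, adjusted p = 0.089). The values of ddx4 (log2 fold change -0.18 ± 0.13, adjusted p = 0.28) and tdrd7a (72.5 ± 6.68 and 66.7 ± 0.884 FPKM, adjusted p = 0.40) did not pass. The whole list had 8 of 26 tested members higher and 6 lower (8 and 6 adjusted over the list alone) and did not pass as a set (camera adjusted p = 0.86, adjusted p = 0.94 with an estimated correlation).

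At stage II, 6180 genes passed, 3521 higher and 2659 lower in mutants, 1740 of them at least 2-fold, with a median log2 fold change of 0.07 over all genes. The share of calls that were higher was 57.0% as deposited, 47.3% after median-of-ratios scaling and 51.7% after quantile normalization.

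The largest rises at stage II included chrnb3b, an acetylcholine receptor subunit gene, from 0.116 ± 0.0566 to 37.3 ± 0.605 FPKM (log2 fold change 5.10 ± 0.10, adjusted p = 6.2e-08). The RNA-binding gene tia1l rose from 3.90 ± 0.944 to 149 ± 0.605 FPKM (4.95 ± 0.13, adjusted p = 2.3e-07) and the tRNA methyltransferase gene trmt2a from 1.21 ± 0.301 to 54.9 ± 4.75 FPKM (4.66 ± 0.12, adjusted p = 2.5e-07). The transcription factor gene gata2b rose from 0.563 ± 0.0461 to 25.7 ± 2.70 FPKM (adjusted p = 1.4e-06), and the ephrin gene efna1b from 1.04 ± 0.256 to 36.7 ± 1.37 FPKM (adjusted p = 1.9e-06). The gene ighv14-1 was listed at 0 in both WT libraries and at 74.2 and 68.8 FPKM in the mutant libraries (adjusted p = 1.0e-06). Of the largest falls, the spindle gene dlgap5 went from 72.2 ± 6.38 to 0.240 ± 0.158 FPKM (-5.89 ± 0.13, adjusted p = 1.2e-07) and kmt5ab from 59.7 ± 5.46 to 0.0689 ± 0.0329 FPKM (-5.82 ± 0.12, adjusted p = 1.2e-07). The genes tmem60, zdhhc4 and fbxl14a were listed at 0 in both mutant libraries, against 54.2 and 50.3, 49.0 and 54.3 and 51.9 and 49.3 FPKM in WT (adjusted p = 6.2e-08, 6.2e-08 and 6.2e-08). The histone acetyltransferase complex gene kansl2 stood at 43.6 and 52.8 FPKM in WT and 0 and 0.0388 FPKM in mutants (adjusted p = 1.2e-07).

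Genes of protein synthesis were lower in mutants at stage II. Of the cytosolic ribosomal proteins, 2 of 85 tested members were higher and 50 lower (2 and 58 adjusted over the list alone). Their median was -0.43 relative to all genes (camera adjusted p = 4.6e-08, adjusted p = 0.85 with an estimated correlation). In this list rpl19 fell from 1574 ± 131 to 859.9 ± 9.68 FPKM (-0.87 ± 0.10, adjusted p = 4.1e-04), rps15a from 960.0 ± 87.5 to 558 ± 18.5 FPKM (adjusted p = 8.0e-04) and rpl32 from 249 ± 63.2 to 6.99 ± 2.62 FPKM (adjusted p = 1.4e-04). Against the list, faub rose from 114 ± 9.34 to 209 ± 1.72 FPKM (adjusted p = 3.0e-04). Translation initiation and elongation had 7 of 72 tested members higher and 34 lower (7 and 35 adjusted over the list alone; relative median -0.29; camera adjusted p = 5.7e-04, adjusted p = 0.14 with an estimated correlation). Of its initiation factor genes, eif3k fell from 157 ± 8.43 to 79.9 ± 4.30 FPKM (adjusted p = 6.2e-05) and eif3eb fell from 20.2 ± 4.52 to 6.67 ± 1.96 FPKM (adjusted p = 9.9e-04). The nuclear-encoded respiratory chain had 4 of 81 tested members higher and 31 lower (4 and 31 adjusted over the list alone; relative median -0.27; camera adjusted p = 6.6e-04, adjusted p = 0.85 with an estimated correlation). Of its complex I genes, ndufs5 fell from 273 ± 24.7 to 149 ± 15.6 FPKM (adjusted p = 0.0010) and ndufa8 rose from 68.4 ± 6.23 to 115 ± 6.21 FPKM (adjusted p = 5.1e-04). The unfolded protein response had 2 of 28 tested members higher and 15 lower (2 and 15 adjusted over the list alone; relative median -0.37; camera adjusted p = 9.4e-04, adjusted p = 0.77 with an estimated correlation). In it dnajb9b fell from 50.7 ± 2.64 to 12.8 ± 0.166 FPKM (adjusted p = 4.9e-05) and sdf2l1 from 112 ± 5.77 to 54.6 ± 1.52 FPKM (adjusted p = 3.3e-05). The proteasome had 3 of 48 tested members higher and 18 lower (3 and 18 adjusted over the list alone; relative median -0.25; camera adjusted p = 0.0017, adjusted p = 0.77 with an estimated correlation). Here psmb5 fell, against its rise at stage I, from 62.1 ± 7.36 to 31.1 ± 2.90 FPKM (adjusted p = 2.6e-04). The calls of these 5 lists held under every other setting run except the estimated correlation.

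Leukocyte markers were higher in mutants at stage II too: 9 of 12 tested members were higher and 0 lower (9 and 1 adjusted over the list alone). Their relative median was 0.82 (camera adjusted p = 0.012, adjusted p = 0.77 with an estimated correlation). The actin-binding gene coro1a rose from 0.476 ± 0.00540 to 3.53 ± 0.433 FPKM (adjusted p = 3.1e-04). The granulosa and theca list had 3 of 5 tested members higher and 1 lower (3 and 1 adjusted over the list alone), camera adjusted p = 0.21. There cyp11a1 rose from 68.0 ± 20.5 to 269 ± 12.6 FPKM (log2 fold change 2.00 ± 0.18, adjusted p = 1.1e-04) and cyp17a1 from 34.4 ± 0.643 to 71.3 ± 2.89 FPKM (adjusted p = 3.8e-05). The stroma, smooth muscle and endothelium list had 3 of 10 tested members higher and 2 lower (3 and 2 adjusted over the list alone), adjusted p = 0.86. The collagen gene col1a1a fell from 1.98 ± 0.262 to 0.333 ± 0.0129 FPKM (adjusted p = 4.8e-04) and the endothelial receptor gene kdrl from 1.73 ± 0.0786 to 0.423 ± 0.315 FPKM (adjusted p = 0.0035). In the testis and sperm list, 2 of 9 tested members were higher and 3 lower (2 and 3 adjusted over the list alone), adjusted p = 0.66, with a median of -0.11 and a mean of 0.14. There spata18 rose from 11.9 ± 0.730 to 113 ± 1.31 FPKM (3.15 ± 0.08, adjusted p = 2.5e-07). Of the 3 tested blood genes 2 were higher and tspo was lower, from 52.2 ± 0.688 to 31.2 ± 1.75 FPKM (adjusted p = 5.4e-04). The 1 tested liver gene, rbp4, was lower (2.07 ± 0.546 to 0.603 ± 0.499 FPKM, adjusted p = 0.014), a call lost without WT replicate 2 or mutant replicate 2 (adjusted p = 0.081 and 0.079).

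Germ cell lists other than the germ plasm were mixed at stage II. The piRNA and Tudor list had 8 of 17 tested members higher and 2 lower (8 and 2 adjusted over the list alone), camera adjusted p = 0.24. The Tudor gene tdrd5 fell from 46.5 ± 0.551 to 5.39 ± 0.164 FPKM (log2 fold change -2.89 ± 0.09, adjusted p = 6.9e-07), while tdrd1 rose from 28.5 ± 2.88 to 69.4 ± 6.19 FPKM (1.25 ± 0.11, adjusted p = 1.2e-04). The oocyte list had 11 of 33 tested members higher and 14 lower (11 and 16 adjusted over the list alone), adjusted p = 0.49. In it figla rose from 9.20 ± 1.19 to 55.3 ± 3.64 FPKM (2.47 ± 0.12, adjusted p = 5.7e-06) and the pluripotency factor gene pou5f3 from 10.3 ± 0.443 to 29.6 ± 2.66 FPKM (adjusted p = 3.6e-04). The egg coat genes zp2.3 and zp2.1 fell from 1149 ± 95.6 to 276 ± 52.6 FPKM (adjusted p = 3.9e-05) and 267 ± 84.8 to 73.9 ± 7.91 FPKM (adjusted p = 5.8e-04). Meiotic prophase had 3 of 11 tested members higher and 3 lower (3 and 3 adjusted over the list alone), adjusted p = 0.96. The gene sycp3 rose from 1.05 ± 0.765 to 11.6 ± 0.144 FPKM (adjusted p = 1.6e-04) and the mismatch repair gene mlh3 fell from 5.93 ± 0.677 to 1.14 ± 0.0482 FPKM (adjusted p = 1.0e-04). The cell cycle list had 9 of 34 tested members higher and 8 lower (10 and 11 adjusted over the list alone), adjusted p = 0.68. In it birc5b was listed at 0 in both mutant libraries against 11.8 and 14.8 FPKM in WT (adjusted p = 4.9e-06). Its paralog birc5a stood at 87.2 ± 3.41 and 96.1 ± 8.57 FPKM (adjusted p = 0.34). Whether the 2 share reads is not given. The spindle checkpoint gene bub3 fell from 241 ± 6.46 to 139 ± 1.59 FPKM (adjusted p = 0.0014).

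No other list passed at stage II. Microtubule motors and tubulins had 18 higher and 9 lower of 59 (19 and 10 adjusted over the list alone), camera adjusted p = 0.49. The hedgehog pathway kinesin gene kif7 rose from 25.3 ± 3.72 to 281 ± 6.00 FPKM (log2 fold change 3.43 ± 0.10, adjusted p = 5.0e-07). Steroid and retinoid metabolism had 5 higher and 1 lower of 13 (5 and 2 adjusted over the list alone), adjusted p = 0.29. In it cyp26a1 rose from 7.34 ± 0.853 to 48.6 ± 1.53 FPKM (2.57 ± 0.12, adjusted p = 5.7e-06) and the estrogen receptor gene esr2a from 1.01 ± 0.101 to 5.38 ± 0.301 FPKM (adjusted p = 1.2e-04). Cholesterol synthesis had 7 higher and 3 lower of 22 (7 and 3 adjusted over the list alone), adjusted p = 0.71. The squalene epoxidase gene sqlea rose from 0.292 ± 0.0204 to 4.49 ± 0.261 FPKM (adjusted p = 4.0e-05). Nuclear pore and transport had 3 higher and 13 lower of 57 (2 and 9 adjusted over the list alone), adjusted p = 0.21. Mitochondrial dynamics and biogenesis had 10 higher and 8 lower of 47 (9 and 7 adjusted over the list alone), adjusted p = 0.67. The mitochondrially encoded genes had 5 higher and 0 lower of 13 (5 and 0 adjusted over the list alone), adjusted p = 0.14. That list passed after quantile normalization (adjusted p = 0.0094) and with only the 4 libraries compared (0.017). Immediate-early and heat shock genes had 9 higher and 4 lower of 31 (9 and 4 adjusted over the list alone), adjusted p = 0.42. The TGF-beta, BMP and Wnt list had 4 higher and 4 lower of 18 (4 and 4 adjusted over the list alone), adjusted p = 0.86.

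**Figure D2:**
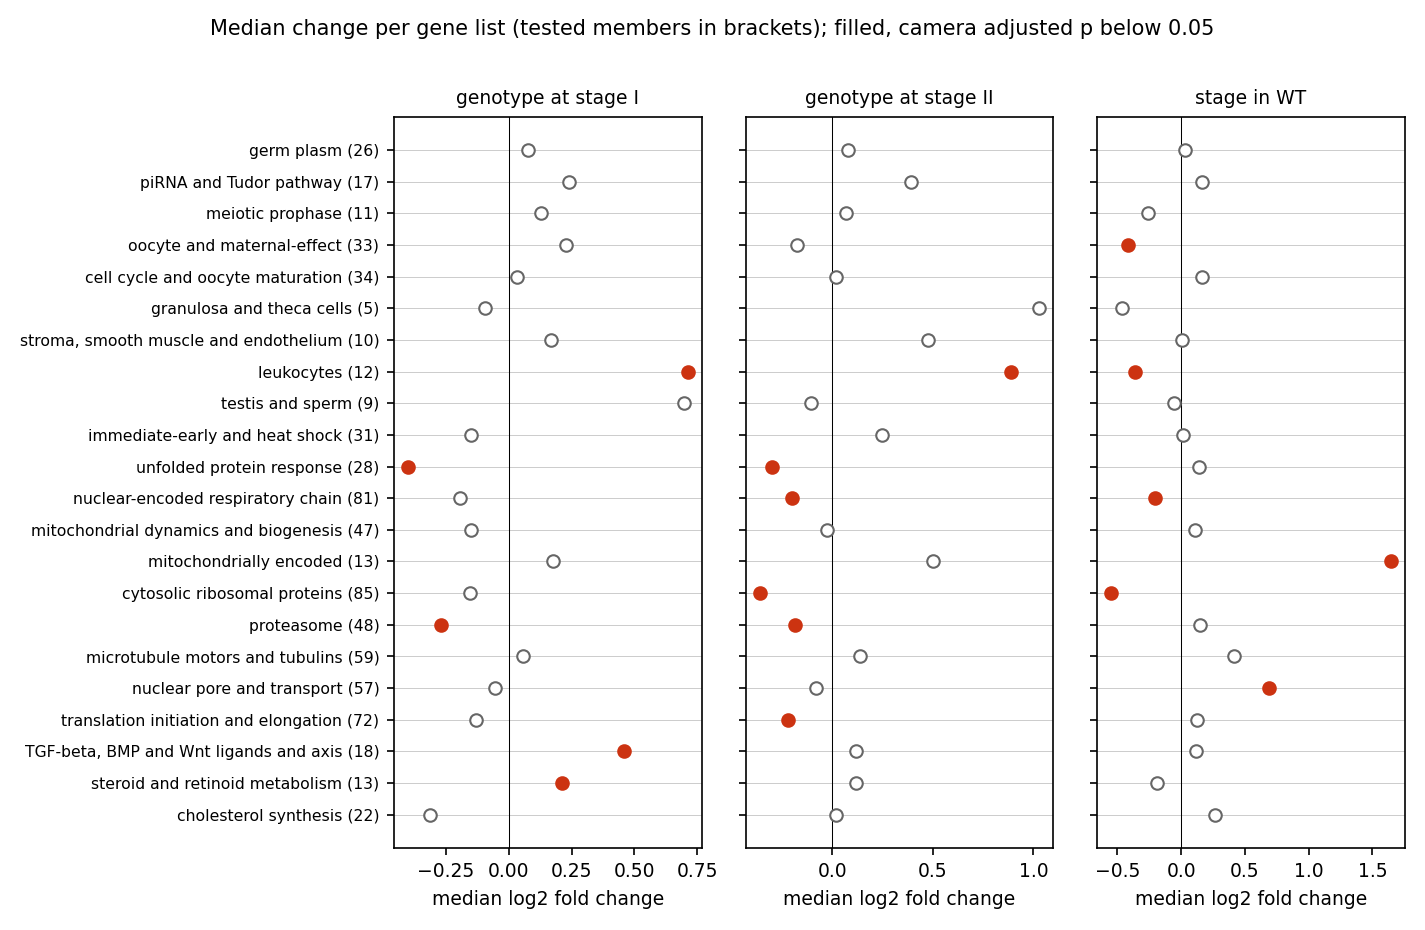
Median log2 fold change (x axis, log2(FPKM + 1) scale) of 22 of the 23 tested gene lists (y axis, tested members in brackets) for the genotype at stage I, the genotype at stage II and the stage in WT; filled points passed camera with the preset correlation. The ribosomal protein list lies at -0.15, -0.36 and -0.55, and the leukocyte list at 0.71, 0.89 and -0.36.

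Genotype effects at the 2 stages were then set side by side. Across the 13862 genes the log2 fold changes at stages I and II correlated weakly (Pearson r = 0.24, Spearman correlation 0.29), and between 0.173 and 0.262 over the 16 pairings of single libraries. These contrasts share no library, and genes are not independent replicates. Of the genes called at both stages, 1155 were higher and 1224 lower at both, where independent lists of these sizes would share 648 and 716, and 290 and 557 went opposite ways, where independent lists would give 489 and 948. The effect was called at stage I alone for 3056 genes and at stage II alone for 2954, which by itself shows no difference between the stages. Genes that rose at both stages included nanos3, figla, sycp3, spata18, kif7 and cyp26a1, and kmt5ab and birc5b were lower at both.

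**Figure D3:**
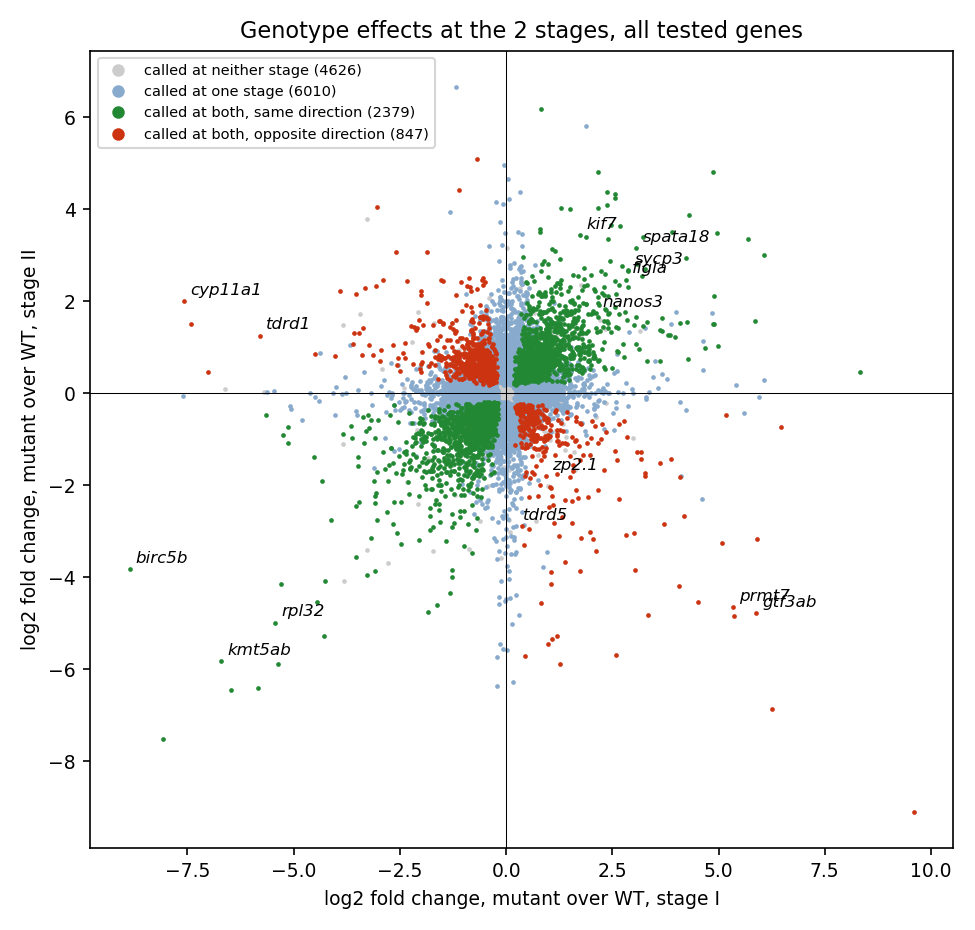
Log2 fold change between mutant and WT oocytes at stage I (x axis) against stage II (y axis), both on the log2(FPKM + 1) scale, for each of the 13862 tested genes (points), coloured by the stages at which the gene passed the threshold. Genes called at both stages in the same direction number 2379 and those called in opposite directions 847.

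Averaged over both stages, which sets 4 mutant libraries against 4 WT libraries within stage, 7234 genes passed, 3472 higher and 3762 lower in mutants, 1222 of them at least 2-fold, and the median of all genes was -0.01. The share of calls that were higher was 48.0% as deposited, 49.1% after median-of-ratios scaling and 50.2% after quantile normalization. The largest rises not yet named were kras, a small GTPase gene (log2 fold change 3.59 ± 0.12, adjusted p = 5.2e-07), and the sialidase gene neu3.2 (3.49 ± 0.11, adjusted p = 4.6e-07). The levels of kras were 1.99 ± 0.665 FPKM in WT and 54.6 ± 3.39 FPKM in mutants at stage I, and 8.64 ± 1.15 and 73.0 ± 3.77 FPKM at stage II. The largest falls included tspan4b, a tetraspanin gene, at 30.5 ± 0.891 and 0.437 ± 0.165 FPKM at stage I and 36.3 ± 7.46 and 0.589 ± 0.167 FPKM at stage II (-4.50 ± 0.13, adjusted p = 3.5e-07). The mitochondrial rRNA methyltransferase gene mrm1 and the zinc finger gene znf989 were listed at 0 in all 4 mutant libraries, with 19.7 and 17.2 and 12.2 and 9.25 FPKM in the WT stage I libraries. Of the 23 tested lists, 6 passed. Ribosomal proteins (2 higher and 50 lower of 85, 2 and 53 adjusted over the list alone, camera adjusted p = 7.8e-05, adjusted p = 0.90 with an estimated correlation) were lower. The respiratory chain (adjusted p = 9.8e-04), the proteasome (9.8e-04), the unfolded protein response (0.0015) and translation (0.027, lost after quantile normalization at 0.073) were lower, and leukocytes (0.0011) higher. With an estimated correlation these 5 lists were at adjusted p = 0.90, 0.57, 0.73, 0.41 and 0.41. Of lists that did not pass, TGF-beta (adjusted p = 0.068), steroid (0.068) and mitochondrially encoded genes (0.088) did on leaving out 1 of several libraries, at 0.038 to 0.050, 0.050 and 0.012 and 0.028. With a filter at a mean of 5 FPKM all 3 passed (0.027, 0.047 and 0.047), with a pseudocount of 5 the TGF-beta and steroid lists (0.039 and 0.049) and after quantile normalization the TGF-beta and mitochondrially encoded lists (0.038 and 0.031).

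From stage I to stage II in WT oocytes, a background against which genotype effects can be read, more genes moved than with the genotype at either stage. Libraries of the 2 stages also differed in oocyte number (about 600 and 150), and the 103 conflicting gene IDs differed in stage I columns alone. Whether both stages were quantified in 1 run is not given, so growth cannot be told apart from input or processing. Ribosomal protein genes were lower at stage II, with 1 of 85 tested members higher and 61 lower (1 and 61 adjusted over the list alone) and a relative median of -0.70 (camera adjusted p = 2.1e-12, adjusted p = 0.71 with an estimated correlation). For example, rps28 fell from 1251 ± 85.8 to 371 ± 61.2 FPKM (log2 fold change -1.76 ± 0.12, adjusted p = 2.8e-05) and rpl38 from 692 ± 56.0 to 209.5 ± 42.7 FPKM (adjusted p = 3.9e-05). Mitochondrially encoded transcripts were higher, with 12 of 13 tested members higher and 0 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.0052, adjusted p = 0.71 with an estimated correlation). Cytochrome b, mt-cyb, rose from 151 ± 58.0 to 754 ± 5.10 FPKM (2.36 ± 0.25, adjusted p = 1.5e-04). Nuclear pore and transport genes were higher, with 38 of 57 tested members higher and 5 lower (38 and 5 adjusted over the list alone) and a relative median of 0.54 (camera adjusted p = 0.0015, adjusted p = 0.71 with an estimated correlation). The Ran-binding gene ranbp10 rose from 1.34 ± 0.350 to 8.22 ± 0.0679 FPKM (adjusted p = 3.1e-04) and the importin gene ipo7 from 73.3 ± 0.272 to 195 ± 9.08 FPKM (adjusted p = 4.9e-06).

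Of the oocyte and maternal-effect list, 6 of 33 tested members were higher and 17 lower (6 and 17 adjusted over the list alone; camera adjusted p = 2.6e-04, adjusted p = 0.68 with an estimated correlation). The egg coat gene zpcx fell from 932 ± 32.3 to 302 ± 5.62 FPKM (log2 fold change -1.62 ± 0.09, adjusted p = 1.3e-05) and btg4 from 673 ± 19.6 to 264 ± 1.01 FPKM (adjusted p = 3.9e-05). The nuclear-encoded respiratory chain had 14 higher and 36 lower of 81 (14 and 36 adjusted over the list alone; camera adjusted p = 0.0010, adjusted p = 0.71 with an estimated correlation). Leukocyte markers had 0 higher and 3 lower of 12 (0 and 3 adjusted over the list alone; camera adjusted p = 0.022, adjusted p = 0.68 with an estimated correlation). The leukocyte call was lost under 6 of the other settings, among them median-of-ratios scaling (adjusted p = 0.061), and without WT stage I replicate 2 (0.067) or WT stage II replicate 1 (0.053). Quantile normalization ended the calls of the ribosomal (0.13), respiratory (0.58) and oocyte lists (0.45). The remaining 17 lists did not pass, and of these the steroid list did without a filter (0.050).

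Of the germ plasm set, buc fell between the stages in WT from 1035 ± 36.8 to 468 ± 40.8 FPKM (log2 fold change -1.15 ± 0.09, adjusted p = 4.6e-05) and nanos3 from 78.8 ± 1.39 to 42.7 ± 1.83 FPKM (-0.87 ± 0.06, adjusted p = 3.2e-05). The genes tdrd7a and ddx4 rose by 0.87 ± 0.10 (adjusted p = 2.7e-04) and 0.51 ± 0.13 (adjusted p = 0.0088). The values of dazl, dnd1 and piwil1 did not pass (adjusted p = 0.064, 0.21 and 0.18), although dazl and piwil1 did under both other scalings. The fall of tdrd6 (adjusted p = 0.038) was lost without any 1 library other than WT stage I replicate 2 (adjusted p = 0.052 to 0.18). The targeted gene znf706 fell by 0.64 ± 0.11 on the log2 scale (adjusted p = 0.0013). In all, 8354 genes passed, 5279 higher and 3075 lower at stage II, 2725 of them at least 2-fold, around a median of 0.15. The share that was higher was 63.2% as deposited, 49.3% after median-of-ratios scaling and 53.4% after quantile normalization. Large single changes again joined high levels to almost none. The chaperone gene cox17 rose from 0.443 ± 0.0733 to 57.0 ± 10.1 FPKM (adjusted p = 1.1e-05). The exonuclease gene isg20 was listed at 0 in both stage I libraries and at 37.4 and 31.2 FPKM at stage II (adjusted p = 4.8e-07). The gene rrm2 (ENSDARG00000078069) rose from 1.29 ± 0.317 to 249 ± 49.2 FPKM (adjusted p = 1.6e-07), while chrnb3b fell from 76.9 ± 5.52 to 0.116 ± 0.0566 FPKM (adjusted p = 7.5e-08) and tia1l from 221 ± 20.1 to 3.90 ± 0.944 FPKM (adjusted p = 2.3e-07).

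Whether the genotype effect differed between the stages was tested by the interaction, the effect at stage II minus that at stage I. The clearest differences were genes that went opposite ways. The piRNA gene tdrd1 and the steroidogenic gene cyp11a1, almost absent from mutants at stage I, were above WT in mutants at stage II (interaction 7.05 ± 0.16, adjusted p = 1.7e-07, and 9.59 ± 0.25, adjusted p = 2.7e-07). In reverse, gtf3ab, thumpd3, foxa and the recombination gene rad52 were higher in mutants at stage I and lower at stage II (-10.66 ± 0.24, -10.21 ± 0.18, -9.07 ± 0.28 and -9.06 ± 0.37, adjusted p = 1.7e-07, 9.1e-08, 7.0e-07 and 3.3e-06). At stage II prmt7 was listed at 0 in both mutant libraries and stood at 27.0 and 21.4 FPKM in WT, the reverse of stage I (adjusted p = 1.7e-07). In the germ plasm set, the interaction passed for dazl (-0.81 ± 0.13, adjusted p = 0.0029), dnd1 (-0.73 ± 0.12, adjusted p = 0.0031) and tdrd7a (-0.64 ± 0.15, adjusted p = 0.012), all lower at stage II relative to stage I. It passed for buc (0.54 ± 0.13, adjusted p = 0.015) and nanos3 (-0.37 ± 0.09, adjusted p = 0.016) only under part of the settings. That of nanos3 turned sign under quantile normalization (0.05, adjusted p = 0.69) and was lost without either mutant stage II library (-0.37, adjusted p = 0.052, and -0.36, adjusted p = 0.057). That of buc was lost after median-of-ratios scaling (0.34, adjusted p = 0.11), without WT stage I replicate 1 (0.50, adjusted p = 0.052) and without mutant stage II replicate 1 (0.48, adjusted p = 0.058). The interaction did not pass for piwil1, tdrd6 or ddx4 (adjusted p = 0.60, 0.15 and 0.060), and that of ddx4 passed without WT stage I replicate 2 (0.72, adjusted p = 0.0039).

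In all, 5039 genes had a called interaction, 3235 above 0 and 1804 below, 2361 of them at least 2-fold, around a median of 0.14. The share above 0 was 64.2% as deposited, 47.1% after median-of-ratios scaling and 52.5% after quantile normalization. They include all 847 genes called in opposite directions at the 2 stages and 617 of the 2379 called in the same direction. Of the 23 lists tested, the ribosomal proteins passed, with 3 of 85 tested members higher and 12 lower (1 and 1 adjusted over the list alone). The relative median was -0.38 (camera adjusted p = 7.9e-04, adjusted p = 0.93 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.64) and without WT stage I replicate 1 (0.097) or WT stage II replicate 1 (0.14). The oocyte list, which did not pass (adjusted p = 0.11), did without WT stage I replicate 2 (0.015), and the TGF-beta list (0.069) did without that library or mutant stage I replicate 1 (0.050 and 0.034), with a pseudocount of 5 (0.038) and without on and off genes (0.045). Over all 5 comparisons, 24 of 115 list tests passed with the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. In 27 of the 115 tests a list's median, mean and test differed in sign, in none of the 24 that passed.

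**Figure D4:**
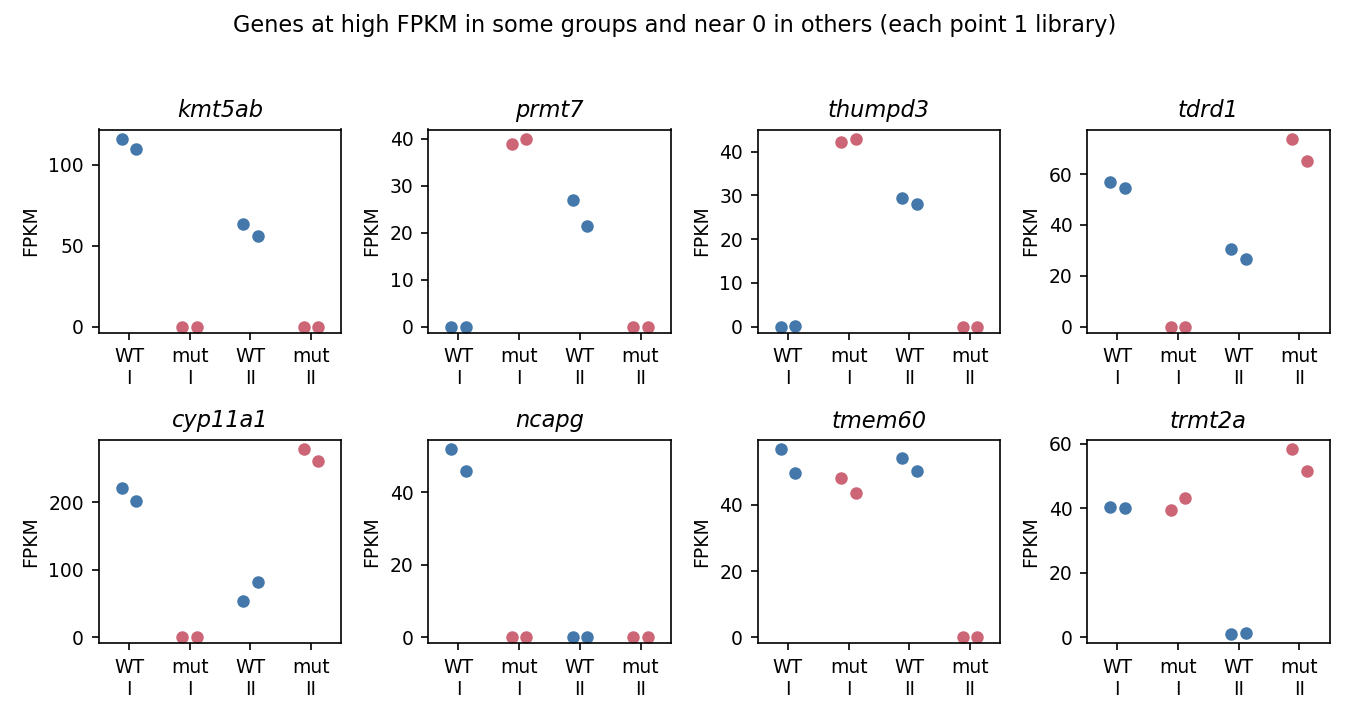
FPKM (y axis) of 8 genes that stood high in some groups and near 0 in others, in WT and mutant (mut) oocytes at stages I and II (x axis; each point is 1 library). The gene kmt5ab is near 0 in all 4 mutant libraries, thumpd3 near 0 in WT stage I and mutant stage II, and tdrd1 near 0 in mutant stage I only.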

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

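The tests of neighbouring genes, of exact 0 values, of the repeat between stages, of growth and of leukocyte markers were chosen after the results had been seen, and that of scaling before. Leaving out the leukocyte markers arhgdig and rac2, 107 genes named here were followed. A difference between the stages in the genotype effect, by the interaction test, drew attention to 66 of the 107, 29 above 0 and 37 below, and to 1 list. Because the naming rule favours large changes, this share is not that of all genes. Interactions are the log2 effect at stage II minus that at stage I.

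In germ cell genes the interaction was nanos3 -0.37, dazl -0.81, dnd1 -0.73, tdrd7a -0.64, buc 0.54 and ca15b -1.23 for the germ plasm, tdrd1 7.05 and tdrd5 -3.13 for the piRNA pathway, sycp1 -1.29, sycp2 -1.36, terb1 1.38 and mlh3 -1.61 for meiosis and pou5f3 1.17, zp2.1 -2.74 and zp2.3 -2.39 for the oocyte list. For the cell cycle it was bub3 -0.78 and fbxo43 -1.005. The interactions of nanos3 and buc were lost without either mutant stage II library (adjusted p = 0.052 and 0.057), and without WT stage I replicate 1 or mutant stage II replicate 1 (0.052 and 0.058), in that order. With a pseudocount of 0.1 those of kmt5ab (0.79, adjusted p = 0.068) and mrm1 (adjusted p = 0.053), near or at 0 in all 4 mutant libraries so that the change in WT sets them, were lost, and after quantile normalization that of psmc1a (0.56, adjusted p = 0.054). In protein synthesis and turnover it was eif1axb -7.20, eif1b -2.80, eif4ea 1.16, faub 0.77, magoh 5.52, gtf3ab -10.66, thumpd3 -10.21, tia1l 5.01 and trmt2a 4.63, with dnajb9b 2.42, pdia6 -1.66, psmb5 -1.78 and psmc1a 0.85 for folding and the proteasome, and ndufa8 1.03 and mff 0.98 for mitochondria. The cytosolic ribosomal protein list had a median interaction of -0.23. Markers of other cells gave coro1a 1.03, cyp11a1 9.59, col1a1a -1.14, fn1a -1.21, kdrl -1.06, krt8 1.67 and tspo -1.02. The steroid and motor genes gave cyp26a1 1.00 and kif7 1.68. The other large changes gave alg14 7.47, chrnb3b 5.79, dlgap5 -7.17, efna1b 4.14, foxa -9.07, gata2b 1.71, kansl2 -5.61, kmt5ab 0.89, kras -1.29, ncapg 5.65, neu3.2 -2.77, rad52 -9.06, smx5 -5.23, rrm2 (ENSDARG00000078069) -7.87 and qdprb2 (ENSDARG00000086859) 3.56. Where a group was listed at 0 in both libraries, the adjusted p of the interaction is given in place of a fold: birc5b 9.5e-06, fbxl14a 7.2e-08, FQ377662.1 5.1e-04, ighv14-1 1.6e-05, isg20 4.3e-04, mrm1 0.011, prmt7 1.7e-07, tmem60 3.4e-07, zdhhc4 2.7e-07 and qdprb2 (ENSDARG00000090118) 2.9e-07. For birc5b, near or at 0 in mutants at both stages, the change in WT sets the interaction, and for FQ377662.1, off in WT at both, the change in mutants does. Both genotypes were off at stage I for isg20, and at stage II for ncapg and this qdprb2 copy. Their interactions therefore show only the effect at the other stage.

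Genes on in one genotype and off in the other (5 FPKM or more in both libraries of one group, under 0.5 in both of the other) numbered 119 at stage I and 96 at stage II. Strain or donor variants shared by neighbouring genes fit in part: of the 163 neighbours of the 93 stage I genes that could be placed, 42 moved at least 2-fold with them, against a mean of 9.42 in random draws (permutation test, p = 0.0001). However, 17 of 88 neighbours also moved with the genes on or off between the stages in WT (9.79, permutation test, p = 0.014), and 84 of 116 genes set 1 group apart rather than a genotype. A strain difference between the genotypes would not give the movement between the stages in WT, while donors that differ between the groups could. In genes expressed at 1 stage, either could set 1 group apart. Whether neighbouring genes moved together for other reasons was not tested. Which fish gave each group is not known here. Exact 0 made up 41.2% of the off values at stage I, under the 50% set for failed estimates, and 54.2% at stage II, which cannot tell, since a true absence also gives 0. Of the 119 stage I genes, 41 (34.5%) were called at least 2-fold the same way at stage II, 22 the opposite way and 56 not at 2-fold. That is under the 50% set, after the data were seen, for a loss of znf706 acting alike at both stages. However, it is above the share of all genes, as 994 of 13862 were at least 2-fold higher and 746 lower at stage II. An effect alike at both stages in part of these genes therefore stays open.

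Lists lower in mutants at stage II were ribosomal proteins, translation, the respiratory chain, the unfolded protein response and the proteasome, all called with the preset correlation and none with an estimated one (adjusted p = 0.14 to 0.85). Scaling of FPKM between libraries did not account for these calls, since all 10 combinations of list and other scaling kept the call with the preset correlation. For translation, the unfolded protein response and the proteasome, a continuation of the WT change from stage I to II did not account for the calls. In all 3 that change (-0.14 to 0.06 over pairings of single libraries) was smaller than the difference of mutant from WT at stage II (-0.43 to -0.19). No later WT stage was sampled, so mutant oocytes further along in growth are not excluded if these lists fall after stage II. The WT change may also hold differences in input or processing between the stages. For the ribosomal and respiratory lists growth cannot be told apart: the ribosomal shift was 61.0% of that with stage in WT, which predicts 0.33 for the nuclear pore list, where -0.15 was seen (-0.18 to -0.08), but the mitochondrially encoded list rose by 0.43 (predicted 0.91), the respiratory shift (-0.27) had the sign of that with stage (-0.36), and the first principal component put mutant stage II (55.0 and 56.6) beyond WT stage II (34.3 and 41.0), although it also put mutant stage I (-54.4 and -50.2) on the other side of WT stage I (-37.4 and -44.9). A loss of znf706 acting directly and a difference in strain, which these libraries do not separate, also stay open.

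Leukocyte markers were higher in mutants at both stages, calls lost with an estimated correlation (adjusted p = 0.49 and 0.77). Leukocytes carried along with the oocytes would raise markers too low to be tested as well, and 7 of the 11 such markers with any signal (63.6%) were higher in mutants at both stages, between the bounds set at 1 in 2 and 2 in 3, so this cannot tell. Markers that reached 1 FPKM only in mutants, such as cd4-1 and coro1a, were tested and so left out of this share, which lowers it beforehand. Their entry through the mutant libraries likewise raises the count of higher markers among those tested. More somatic cells of every kind stays open as well: in 2 of 4 combinations of the granulosa and stroma lists with a stage more called members were higher than lower, and their 5 and 10 tested genes are too few to tell. The relative medians at stages I and II were -0.02 and 0.96 for granulosa and theca and 0.24 and 0.41 for stroma. Carried leukocytes, other somatic cells and expression in oocytes are not separated.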

How the results depend on the processing

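Each result was recomputed under those of 25 alternatives that apply to it, changing 1 choice at a time, 2 of the 25 (conflicting gene IDs entered at the mean of their values, and on and off genes left out) added after the data were seen. Counts of calls stayed within 1.5 times of those reported under every alternative but a 2-fold threshold, which by construction left 1835 genes at stage I, 1740 at stage II, 1222 averaged, 2725 for stage in WT and 2361 for the interaction. The correlation of the 2 genotype effects, 0.240, was 0.286 as a Spearman correlation and 0.270 without on and off genes. Camera with an estimated correlation called 0 of the 24 list tests; by construction that test takes each list's correlation from these 8 libraries. Leaving out 1 library at a time, where the lone library left is assumed to vary like the other groups, gave 4443 to 6104 calls at stage I, 4257 to 6246 at stage II, 6100 to 6769 averaged, 6849 to 8158 for stage in WT, 3626 to 5029 for the interaction, 22 to 28 list tests and a correlation of 0.211 to 0.260. Over genes and settings, 14647 results kept their sign and their side of the threshold, which includes genes called neither before nor after. Calls were lost in 617, of which 192 by construction under the 2-fold threshold, and gained in 65. Below the threshold 85 changed sign, and 2 turned: the interaction of nanos3 under quantile normalization (0.0540), and qdprb2 (ENSDARG00000086859) at stage II without WT replicate 1 (0.38, in a range of -1.33 to 0.38). The cause was not tested. Replicate numbers are shared by all groups. Deviations of same-numbered libraries correlated across genes at -0.04 to 0.06, so no shared shift was seen. Whether same-numbered libraries shared fish or a run is not given. With the number as a replicate block, 5965, 5887, 7005, 8153 and 4725 genes and 23 list tests passed; within genotype, 7699 for stage in WT and 4034 for the interaction. With only the 4 libraries compared, 5471 and 5810 passed at stages I and II. Depth was estimated only relative to 1 library and only near equal depth, which limits what values near 0 show.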

Other observations

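The tests of neighbours of on and off genes in this part, and the genes named in its first 2 paragraphs, were chosen after the values had been seen. Some genes with large changes had neighbours that changed with them, and others did not. Of the 3 placed genes on each side of kmt5ab, which was near 0 in all mutant libraries, the nearest gene C5H12orf65 had log2 fold changes of -1.83 and -4.76 at stages I and II, rilpl2, a regulator of cilia, -1.94 and -1.41, the glucuronosyltransferase gene ugt2a5 -1.36 and -1.49 and the m6A reader gene ythdc1 -1.55 and -2.80, and all of these passed at both stages, while mthfd2 stood at -1.04 and -0.42, not passing at stage II, and arl6ip4 rose (0.70 and 0.88). Near birc5b, zgc:153867 stood at -3.67 and 1.04, b4galnt1a at -3.00 and -0.58, tac3a at -0.84 and 0.60 and slc26a10 at 1.18 and 0.83. Near tdrd1 (-5.80 and 1.25), ccdc186 stood at -1.44 and 0.12, atrnl1b at -0.94 and 0.47 and afap1l2 at -0.93 and 0.52. There dclre1a stood at -0.90 and 0.02, and trub1 at 0.23 and -0.58. The genes directly next to cyp11a1 and rpl32 changed little at stage I (stoml1 0.07 and stra6 -0.08, ssuh2.4 -0.15 and sec13 -0.38). Beyond ssuh2.4, zgc:171679 fell with rpl32 (-4.13 and -2.75 at stages I and II), while slc6a6b on the other side rose (0.59 and 1.11). Near cyp11a1, which fell at stage I and rose at stage II, ush1c stood at 0.54 and 1.30, abcc8 at 0.38 and 0.87 and hexa at -0.46 and -0.25.

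Of the 116 genes whose 4 groups could all be read as on or off, 17 followed the genotype at both stages (8 on in WT alone, 9 on in mutants alone), 8 followed the stage, 7 were crossed, and in 84 a single group stood apart, most often as off in mutant stage II alone (30 genes). Of the 96 stage II genes 75 could be placed, and 24 of their 129 neighbours moved with them (mean of random draws 6.17, permutation test, p = 0.0001). Between the stages in WT 69 genes were on or off, and 50 could be placed. Reads moved between neighbouring genes would make neighbours move against the stage I genes. Among the counted neighbours this happened in 9 cases, with a mean of 9.61 in random draws. Overlapping genes and adjacent genes that were both on or off were not counted, so reads moved between those stay open. For reads shared with a paralog, the partner compensated in 3 of 47 a and b pairs over both genotype comparisons, so such sharing did not account for most of these pairs. Copies with the same symbol, such as those of qdprb2, and genes without an a or b partner were not covered. However, birc5b at stage II was 1 of these 3, so its fall at that stage may in part be reads shared with birc5a.

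As a hypothesis, variants linked to the znf706 allele were tested by the 50 tested genes on each side of znf706 in the reference order. The median absolute averaged log2 fold change of this window was 0.261, below the 95th percentile of 0.366 over 9756 windows and at percentile 30.7, so the genes around znf706 did not stand out. Of the 3 nearest placed genes on each side, psmg2 was at -0.43 and -0.45 at stages I and II (adjusted p = 0.0030 and 0.0027), ptpn2b at -0.25 and -0.24 (0.022 and 0.025), ywhaz at 0.24 and 0.17 (0.013 and 0.043), pabpc1b at 0.07 and 0.65 (0.81 and 0.033), and rnf19a and seh1l did not pass at either stage.

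Other splits of the 8 libraries within stages were too few for a share under 0.05. The real split gave 7234 calls, and the highest of the others, which is that of the interaction, 5039.

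Mitochondrially encoded transcripts took 0.314% to 0.502% of summed FPKM in stage I libraries, 1.24% and 1.30% in WT stage II and 1.76% and 1.84% in mutant stage II. Ribosomal protein transcripts took 10.4% to 11.7% at stage I, 9.33% and 8.23% in WT stage II, and 6.79% and 7.37% in mutant stage II.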
